A study of Homo sapiens with 24 samples.

How the data were processed

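Total RNA from 24 cultures of the human U937 cell line was made into Illumina TruSeq RNA libraries and sequenced, per the labels' protocols. The libraries comprised 10 lines with type 1 p53 mutants and the type 3 line R273H, each with DMSO or with 1 µg/mL arsenic trioxide (ATO) for 24 h, and the p53-null and wild-type p53 lines with DMSO. Groups, lines and treatments were taken from the labels. There was 1 library for each line and treatment, and no label gives a batch or date.

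The authors deposited a single table of gene-level FPKM values (read fragments scaled by gene length and by the library total), printed to 2 decimals, for 60612 Ensembl gene identifiers in 24 libraries. Cutadapt 1.9.1, HISAT2, HTSeq and the genome build hg38 are named in the submitters' processing notes, which give no order or settings. The annotation, the strandedness of counting and any filter are not given in the sources used here. Because FPKM divides by gene length and by the library total, a gene's value depends on the annotated length, and a strong rise of abundant genes lowers the values of all others. Gene symbols came from a list that pairs Ensembl identifiers with current symbols, and coordinates and lengths from GENCODE release 29 (GRCh38). Of the identifiers, 60401 had a symbol and 58394 were in that annotation. Without a stated strand, reads of overlapping genes cannot be separated, so values of small RNAs that lie within longer genes are uncertain.

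Read depth was estimated from the spacing of low FPKM values. In genes 100 to 300 nt long with up to 5 reads, between 332 and 567 genes per library, values fell on whole multiples of the value of 1 read, within a rounding tolerance of 0.005 FPKM, for 77.4 to 85.9% of genes, against 2.63 to 3.82% by chance. The estimates lay between 13880000 and 20120000 reads per library, and averaged 17690000 ± 1891554 with DMSO and 17010000 ± 1638054 with ATO (SD, n = 10 type 1 lines). At these depths 1 read in a 1 kb gene is worth 0.0497 to 0.0720 FPKM, and 3 reads are worth 0.149 to 0.216 FPKM. The reads behind named genes of 300 nt or less were estimated from FPKM, length and depth. Between 10836 and 11658 genes per library reached 1 FPKM. The 10 most abundant genes held 12.6 to 18.6% of the FPKM total. No pair of libraries had identical values.

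Expression was analysed as log2(FPKM + 0.5) for the 11147 genes with a mean of 1 FPKM or more over the 24 libraries. On this scale the fold changes of low genes are understated. limma 3.58.1 in R 4.3.3 was used, with moderated variances that follow the mean expression and Benjamini-Hochberg adjustment at 0.05. The ATO response of the type 1 lines was fitted over 20 libraries with the line as a block. The difference of the R273H response from that response was an interaction term over 22 libraries. Untreated type 1 lines were compared with the p53-null and the wild-type libraries in a fit over 13 untreated libraries. In the latter 3 comparisons the lone library or pair was assumed to vary like the 10 type 1 lines. Wild-type against p53-null, and the R273H pair on its own, have 1 library per condition and were described by values. For these, the median of each gene list was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

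The 26 gene lists, the tests of the main comparisons, the named-gene rule and most of the alternatives were fixed before the data were examined. The relations with the cell cycle genes and several tests of explanations were chosen afterwards. The 22 lists with at least 5 measured genes were tested with camera in limma at its preset correlation of 0.01, with an estimated correlation beside it, and with fry. The mean change of each list was also computed per line and tested over the 10 type 1 lines by an exact two-sided sign-flip permutation test with 1024 flips, whose smallest p is 0.00195. R273H was placed among the 11 mutant lines by exact permutation of the line labels, where the smallest p is 0.0909, so no placement could pass 0.05. Correlations over the 10 lines had 100000-resample permutation p-values. Lists of lymphoid, erythroid and megakaryocyte, epithelial, and fibroblast and endothelial markers were included as checks for other cells and had too few measured genes for a test.

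Most named genes followed a fixed rule. CDKN1A, MDM2, BBC3, BAX, FAS, TP53I3, GDF15, HMOX1, MT2A and GAPDH were always named. For ATO in the type 1 lines the rule took the 10 highest and 10 lowest fold changes among genes past the threshold with the same direction in all 10 lines. For comparisons with a lone library it took the 6 highest and 6 lowest differences past the threshold, and for single pairs the 10 highest and 10 lowest among genes with 5 FPKM or more in the higher library. For each list it took up to 4 members with the smallest adjusted p. Some other genes, such as PMAIP1, were named outside this rule. Clone names, pseudogene names and unofficial symbols were left out. Results for a few other genes that the rule took, and tests that need them, are not reported here.

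The pairing of treated with untreated libraries rests on the line names in the labels. As a check, deviations from the group means correlated between the libraries of the same line at r = -0.071 to 0.606, and 3 of 10 lines correlated best with their own partner. The limma models were tested on simulated data with known changes. For the ATO response in type 1 lines (11063 genes simulated), 79.1% of changes of 0.5 on the log2 scale and 100% of changes of 1 or 2 were recovered, with 9 of 190 calls false. For the R273H difference (11057 genes), 14.9% of changes of 1 and 90.9% of changes of 2 were recovered, with 11 of 81 calls false. For type 1 against p53-null (11055 genes), 39.3% of changes of 1 and 100% of changes of 2 were recovered, with 5 of 85 calls false. Neither of these designs recovered any change of 0.5. The simulated effect of a line was shared by its DMSO and ATO libraries, so the ATO change itself did not vary between lines. In the real data it did, as for CDKN1A with an SD of 0.95 (n = 10 type 1 lines). The recovery in both ATO comparisons is therefore likely too high, and a lack of called genes does not exclude changes of 2.

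The alternatives were pseudocounts of 0.1 and 1, no expression filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, robust variance moderation, no line block, a 2-fold minimum, an estimated correlation in the list tests, the median over p53 targets, the p53 targets without the stress genes ATF3, SESN2, DDIT4 and GDF15, and leaving out each type 1 line in turn. Of these stress genes, DDIT4 is not in the p53 target list and GDF15 is below the expression filter. That setting therefore removed at most ATF3 and SESN2 from the score. After the data were seen, sets of lines whose libraries stood apart were also left out (P142L with V272A, and L130F with L130R and F270I), further settings were run for the list tests, P142L was left out for the always-named genes, and the p53 score was computed on the targets at least 2-fold higher in wild-type. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9.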

Results

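Gene expression was measured by RNA sequencing in U937, a human cell line from a myeloid malignancy with monocytic features. The lines expressed no p53, wild-type p53, 1 of 10 p53 mutants named type 1 in the labels (L130V, L130F, L130R, P142L, V143M, M237V, F270I, F270V, V272M and V272A), or the type 3 mutant R273H. The criterion behind these types is not given in the sources used here. Each mutant line was treated for 24 h with the vehicle DMSO or with 1 µg/mL arsenic trioxide (ATO), a drug used against acute promyelocytic leukemia. The p53-null and wild-type lines received DMSO only. The series asked what transcription the mutants drive once cells receive ATO, with the p53-null and wild-type lines as the references for absent and normal p53. There were 24 libraries, 1 for each line and treatment, so the 10 type 1 lines served as replicates of each other and the p53-null, wild-type and R273H values have no replicates. Estimated depth was 13880000 to 20120000 reads per library, and values are the FPKM deposited by the authors. The limma, fry and sign-flip p-values measure the spread between these lines. Camera p-values instead compare a list with other genes. At the preset correlation they treat genes as nearly independent, so small values do not stand for replication over lines. Placement and permutation p-values come from rearranged line labels or values. Fold changes on the log2(FPKM + 0.5) scale understate those of genes near 0.5 FPKM.

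The comparison of ATO with DMSO in the type 1 lines asks which genes respond to the drug where a type 1 mutant is present. Genes that wild-type p53 activates rose with ATO in the type 1 lines. CDKN1A, the p21 inhibitor of cyclin-dependent kinases (ENSG00000124762, chromosome 6, 36676460 to 36687339, GRCh38), rose from 21.9 ± 30.7 to 93.8 ± 47.2 FPKM (SD, n = 10), against 7.38 FPKM in the p53-null line and 74.5 in the wild-type line. Its log2 change was 2.48 ± 0.25 (SE, adjusted p = 2.9e-06). The untreated P142L library already held 108.3 FPKM of CDKN1A, while the other 9 untreated type 1 lines held 6.18 to 21.1 FPKM and averaged 12.4 ± 4.84. DINOL overlaps CDKN1A on the opposite strand. MDM2, the ubiquitin ligase that degrades p53 (chromosome 12, 68808176 to 68850686), rose from 4.76 ± 1.10 to 16.2 ± 5.85 FPKM, a log2 change of 1.62 ± 0.17 (adjusted p = 3.4e-06), against 3.35 FPKM in p53-null and 16.3 in wild-type cells.

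Of 65 measured members of the p53 target list, 56 rose and 2 fell, over all genes and adjusted over the list alone. The mean change per line was 0.62 ± 0.26 on the log2 scale (SD, n = 10), from 0.35 in M237V to 1.12 in V272M, and was above 0 in 10 of 10 lines (exact sign-flip p = 0.00195, adjusted 0.00286). The list moved more than other genes (camera adjusted p = 1.3e-09), but not with a correlation estimated from the data (adjusted p = 0.367 with an estimated correlation). The members that fell were TRAF4 (-0.33) and STEAP3 (-0.35). Among the targets for cell cycle arrest and feedback, 9 of 9 measured genes rose, over all genes and adjusted over the list alone, with a mean log2 change of 1.45 ± 0.52 (camera adjusted p = 1.3e-04, adjusted p = 0.367 with an estimated correlation). GADD45A, a growth arrest gene, rose by 1.75 ± 0.12 on the log2 scale from 2.64 to 9.96 FPKM, and ZMAT3, an RNA-binding p53 target, by 2.23 ± 0.16 from 0.881 to 5.85 FPKM. CCNG1 (cyclin G1) rose by 0.71 ± 0.06, and BTG2, an antiproliferative gene, by 2.00 ± 0.24. Of 10 measured apoptosis targets, 7 rose and 1 fell, over all genes and adjusted over the list alone (mean log2 0.52, camera adjusted p = 0.021, adjusted p = 0.423 with an estimated correlation). BBC3, which encodes the pro-apoptotic protein PUMA, rose from 3.12 ± 0.57 to 7.02 ± 1.39 FPKM, and BAX, a pore-forming protein of the mitochondrial membrane, from 27.3 ± 6.61 to 49.0 ± 7.57 FPKM. The death receptor FAS rose from 1.98 ± 0.52 to 5.06 ± 1.94 FPKM, and the death receptor TNFRSF10B by 0.91 ± 0.12 on the log2 scale. PMAIP1 (NOXA) had a log2 change of 0.02 (adjusted p = 0.766). Of 13 measured repair and metabolism targets, 11 rose and 1 fell, over all genes and adjusted over the list alone (mean log2 0.47, camera adjusted p = 0.0066, adjusted p = 0.423 with an estimated correlation), among them XPC, a sensor of DNA damage (0.86 ± 0.09), and RRM2B, a ribonucleotide reductase subunit (1.01 ± 0.10). TP53I3 and GDF15 were below the expression filter. TP53I3 averaged 0.179 FPKM with DMSO and 0.228 with ATO in the type 1 lines. GDF15 averaged 0.063 and 0.467 FPKM (exact sign-flip p = 0.0039), with 2.38 FPKM in treated P142L.

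**Figure D1:**
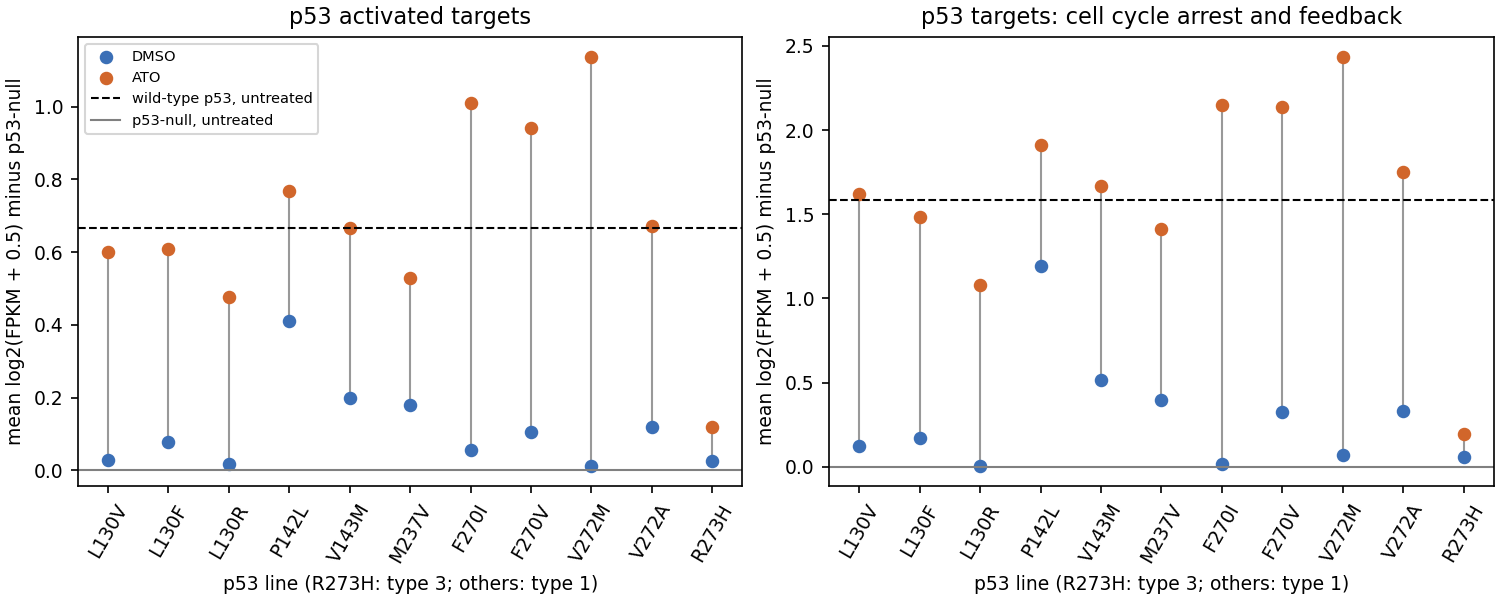
Mean log2(FPKM + 0.5) of p53 target genes minus the p53-null library for each mutant line with DMSO and with ATO, with all targets in the left panel and the arrest and feedback targets in the right panel; the dashed line is the wild-type library. With ATO the 10 type 1 lines lie between 0.48 and 1.14 for all targets, R273H lies at 0.12, and untreated P142L stands above the other untreated lines at 0.41.

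Genes of the oxidative stress and metal responses rose with ATO in the type 1 lines, and HMOX1, MT2A and FTH1 had the highest fold changes of single genes with an official symbol. With a pseudocount of 0.1 the log2 change of APOBEC3H (3.21) lay above those of MT2A (2.94) and FTH1 (2.87). HMOX1, heme oxygenase 1 (ENSG00000100292, chromosome 22, 35380361 to 35394214), rose from 5.33 ± 2.59 to 206 ± 146 FPKM (SD, n = 10), a log2 change of 4.93 ± 0.25 (SE, limma adjusted p = 3.5e-08). MT2A, a metal-binding metallothionein (ENSG00000125148, chromosome 16, 56608199 to 56609497), rose from 59.1 ± 9.63 to 507 ± 281 FPKM (adjusted p = 5.6e-07), and FTH1, the ferritin heavy chain, from 151 ± 54.5 to 1119 ± 390 FPKM (adjusted p = 2.0e-08). The p53-null and wild-type libraries, which had no ATO, held 4.71 and 7.46 FPKM of HMOX1 and 67.9 and 40.1 FPKM of MT2A. Of 19 measured targets of the antioxidant regulator NRF2, 15 rose and 1 (PRDX1, -0.20) fell, over all genes and adjusted over the list alone, with a mean log2 change of 0.75 ± 0.13 (camera adjusted p = 2.6e-05, adjusted p = 0.367 with an estimated correlation). GCLM, a subunit of the enzyme that limits glutathione synthesis, rose from 9.39 to 18.7 FPKM. In the metallothionein list 6 of 6 measured genes rose, over all genes and adjusted over the list alone (mean log2 1.54 ± 0.55, camera adjusted p = 8.9e-04, adjusted p = 0.367 with an estimated correlation), among them MT1F, MT1E and the zinc exporter SLC30A1. The lines were split, with list means of 2.30 to 2.35 in L130F, L130R and F270I and 0.92 to 1.36 in the other type 1 lines. Heat shock genes moved in both directions, with 3 rising and 9 falling of 17 over all genes and adjusted over the list alone (mean log2 -0.16, camera adjusted p = 0.0083, adjusted p = 0.367 with an estimated correlation). The mitochondrial chaperones HSPD1 (-0.61) and HSPE1 (-0.43) fell, and the inducible HSP70 genes HSPA1A (0.39) and HSPA1B (0.26) rose. GAPDH, a common reference gene, was at 1753 ± 109 and 1704 ± 147 FPKM (adjusted p = 0.526).

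**Figure D2:**
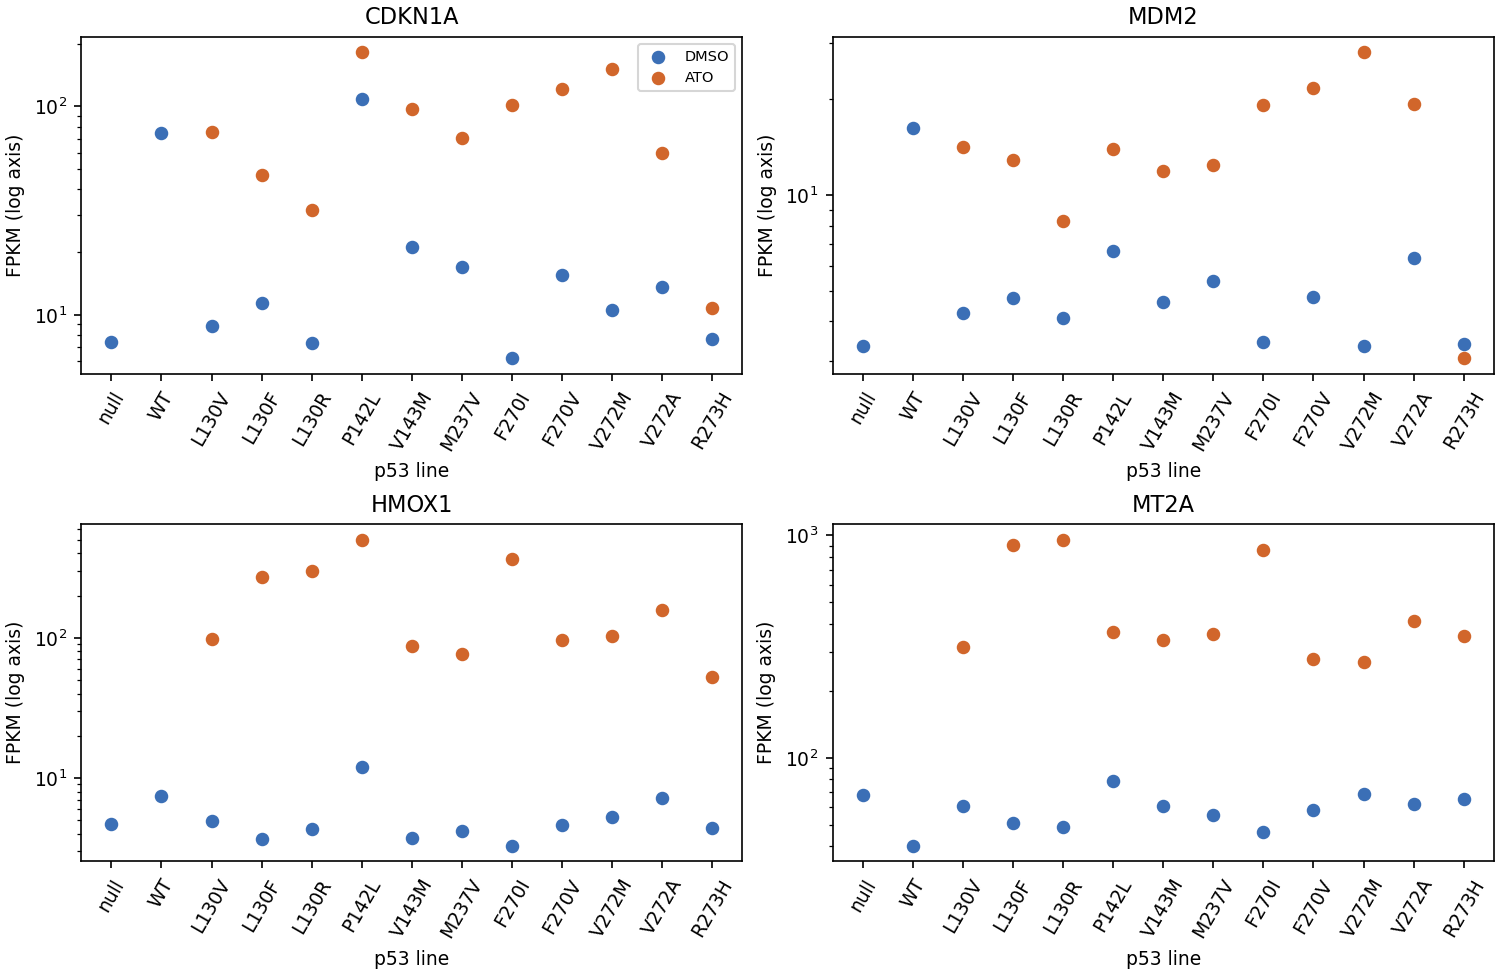
FPKM of CDKN1A, MDM2, HMOX1 and MT2A on a log axis in every library, with p53-null and wild-type cells (DMSO only), the 10 type 1 lines and R273H, each mutant line with DMSO and with ATO. HMOX1 and MT2A are higher with ATO in every mutant line including R273H, where CDKN1A is 7.67 and 10.8 FPKM and MDM2 is 3.40 and 3.06 FPKM.

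Genes of DNA replication and cell division fell with ATO in the type 1 lines. MCM7, a subunit of the replicative helicase (chromosome 7, 100092728 to 100101940), fell from 124 ± 4.72 to 42.3 ± 7.21 FPKM (SD, n = 10), a log2 change of -1.56 ± 0.07 (SE, limma adjusted p = 2.0e-08). This was the lowest log2 change among genes with an official symbol that moved the same way in all 10 lines, and the gene overlaps AP4M1 and the microRNA genes MIR25, MIR93 and MIR106B. The rank depends on the setting. Over the alternative settings the log2 change of MIR219A1 reached -2.54, while that of MCM7 lay between -1.59 and -1.45. Of 28 measured G1/S genes, 27 fell and 0 rose, over all genes and adjusted over the list alone, and their mean log2 change was -0.49 ± 0.21, below 0 in 10 of 10 lines (camera adjusted p = 1.0e-09, adjusted p = 0.367 with an estimated correlation). The helicase subunit gene MCM3 (-0.66 ± 0.06) and the replication factor gene MCM10 (-0.63 ± 0.05) were among them. Of 29 measured G2/M genes, 26 fell and 0 rose, over all genes and adjusted over the list alone, and the mean was -0.38 ± 0.22, below 0 in 9 of 10 lines (camera adjusted p = 1.9e-07, adjusted p = 0.367 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 146 to 86.5 FPKM, and CKS2, a cyclin-dependent kinase subunit, from 148 to 91.9 FPKM.

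Cholesterol synthesis genes fell as well, 19 of 20 with 0 rising, over all genes and adjusted over the list alone (mean log2 -0.53 ± 0.27, camera adjusted p = 1.8e-07, adjusted p = 0.367 with an estimated correlation). INSIG1, a sterol-sensing regulator, fell from 241 to 97.7 FPKM and IDI1, an isomerase of isoprenoid synthesis, by 0.65 ± 0.06 on the log2 scale. FASN (fatty acid synthase) fell from 165 to 59.2 FPKM. Of 16 measured targets of the stress regulator ATF4, 2 rose and 12 fell, over all genes and adjusted over the list alone (mean log2 -0.18, camera adjusted p = 0.0043, adjusted p = 0.423 with an estimated correlation). The amino acid transporter gene SLC7A5 (-0.71) fell and DDIT3 (0.59) rose. Chaperones of the endoplasmic reticulum (2 rising and 10 falling of 16, or 2 and 11 adjusted over the list alone; mean log2 -0.27) included HSPA5, which fell from 338 to 234 FPKM (list camera adjusted p = 0.021, adjusted p = 0.442 with an estimated correlation). Of 31 proteasome genes, 15 fell and 0 rose, over all genes and adjusted over the list alone, by small amounts such as -0.17 for PSMD7 and -0.26 for PSMB5 (camera adjusted p = 0.0014, adjusted p = 0.401 with an estimated correlation).

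Markers of monocyte differentiation rose with ATO in the type 1 lines, 10 of 13 with 2 falling, over all genes and adjusted over the list alone (mean log2 0.63 ± 0.16, camera adjusted p = 0.0015, adjusted p = 0.367 with an estimated correlation). TYROBP, a signalling adaptor of myeloid cells, rose from 19.3 to 39.7 FPKM, and S100A8, which encodes a calcium-binding protein of monocytes and neutrophils, rose by 1.67 on the log2 scale. Lysozyme (LYZ) fell from 2434 to 1677 FPKM and the Fc receptor gene FCGR1A by 0.39 on the log2 scale. Untreated P142L stood 1.11 above the p53-null line in the mean of this list, while the other untreated type 1 lines lay between -0.08 and 0.08. Azurophil granule genes moved both ways, 3 up and 3 down of 9, over all genes and adjusted over the list alone (mean log2 -0.19, camera adjusted p = 0.734), with PRTN3 (proteinase 3) falling from 463 to 193 FPKM and CD63 rising by 0.62 on the log2 scale. Of 10 interferon-stimulated genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone; mean log2 0.37, camera adjusted p = 0.021, adjusted p = 0.367 with an estimated correlation), among them IRF7 (0.78) and IFIT3 (0.71). Histone genes (4 rising and 1 falling of 6, over all genes and adjusted over the list alone) included H2BC12, which rose from 20.03 to 47.4 FPKM (mean log2 0.72, camera adjusted p = 0.029, adjusted p = 0.367 with an estimated correlation). Ribosomal protein genes rose slightly, 26 of 36 with 0 falling, over all genes and adjusted over the list alone (mean log2 0.15, camera adjusted p = 5.7e-04, adjusted p = 0.442 with an estimated correlation), as in RPS19 (0.41) and RPL11 (0.26). Lists of NF-kB targets (3 of 8 rose, 0 fell; mean log2 0.18, camera adjusted p = 0.162), immediate early genes (4 of 9 rose, 1 fell; 0.22, 0.273), glycolysis and hypoxia genes (2 of 18 rose, 7 fell; -0.07, 0.086) and mitochondrial transcripts (1 of 13 rose, 0 fell; 0.09, 0.494) did not pass camera, and their counts were the same adjusted over the list alone. The means of the NF-kB and immediate early lists were nonetheless above 0 in 10 of 10 lines (exact sign-flip p = 0.00195, adjusted 0.00286, for each), and both passed fry, which does not compare a list with other genes (adjusted p = 0.0026 and 0.0095). The mitochondrial list mean was -0.02 with quantile normalization. Glycolysis and hypoxia genes passed camera without the expression filter. Without L130F, L130R and F270I both they and the mitochondrial transcripts passed. Examples are NFKBIA (0.39), KLF6 (0.74), LDHA (-0.59) and MT-CO1 (0.27). Among markers of other cells, 4 lymphoid, 1 erythroid or megakaryocyte, 0 epithelial and 1 fibroblast or endothelial gene passed the expression filter, the highest being NKG7 (106.9 FPKM), KLF1 (1.12), MUC1 (0.57, below the filter) and PECAM1 (24.7), of which NKG7 and PECAM1 are also expressed in myeloid cells.

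**Figure D3:**
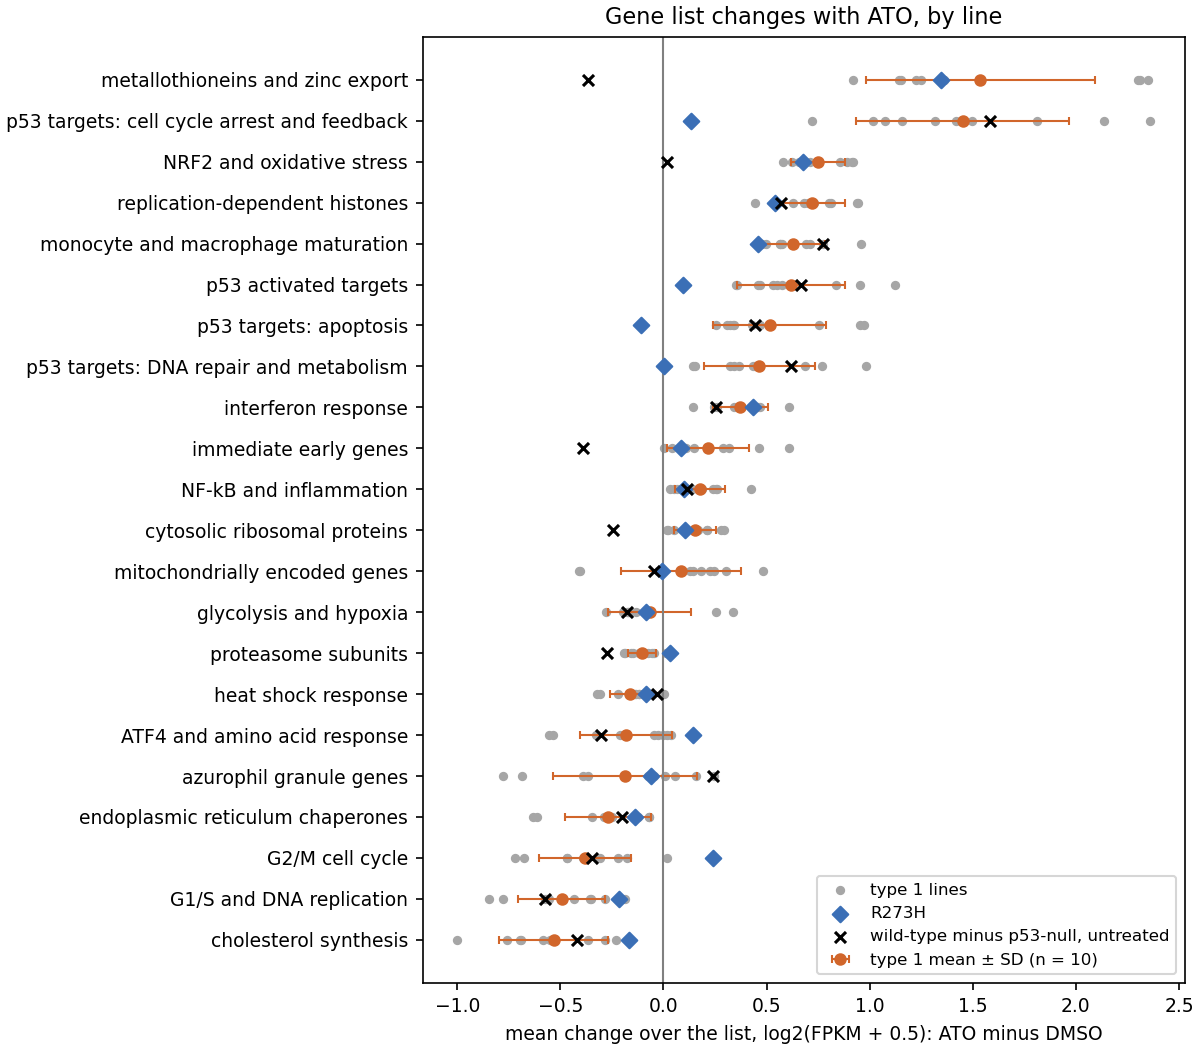
Mean log2 change with ATO of the 22 measured gene lists in each type 1 line (grey points), their mean and SD over 10 lines (orange), and R273H (blue diamonds), with wild-type minus p53-null, both untreated, as black crosses. R273H lies within the type 1 lines for NRF2 targets (0.68) and metallothioneins (1.35) and below all of them for p53 targets (0.09); G2/M genes average -0.38 in the type 1 lines and 0.24 in R273H.

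In all, 7056 of 11147 tested genes changed with ATO in the type 1 lines at a limma adjusted p under 0.05, 3918 higher and 3138 lower. Most changes were small, and 145 of them reached 2-fold, 129 higher and 16 lower. Among genes with an official symbol, the 10 highest fold changes that went the same way in all 10 lines were those of HMOX1, MT2A, FTH1, CDKN1A, ZMAT3, SBF2 (2.18), TRIM22 (2.02), BTG2, APOBEC3H (2.00) and GPR34 (1.93). The 10 lowest were MCM7, MIR219A1 (-1.56), FASN (-1.48), PRTN3 (-1.41), CTXN1 (-1.34), INSIG1 (-1.32), the MHC class II gene HLA-DRA (-1.19), BALR6 (-1.16), CTDSP1 (-1.12) and FGFBP3 (-1.11). MIR219A1 rests on an estimated 0 to 8 reads per library, and in M237V on 1 read with either treatment, where its direction follows from depth alone. Of the 22 lists, 17 passed camera at its preset correlation, 10 higher and 7 lower, 19 passed fry, and 0 passed with an estimated correlation. No untreated and treated pair of p53-null or wild-type cells was part of the series, so the response to ATO without a p53 mutant was not measured.

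The R273H pair asks whether the response depends on the type of mutant, and its p53 target values with ATO lay near those of p53-null cells. CDKN1A was at 7.67 FPKM with DMSO and 10.8 with ATO, MDM2 at 3.40 and 3.06, BBC3 at 3.59 and 3.50, BAX at 22.6 and 26.5, and FAS at 1.84 and 1.39 FPKM. The mean log2 difference over p53 targets was 0.09 in R273H, below each of the 10 type 1 lines (0.62 ± 0.26, SD), and over arrest and feedback targets 0.13, again below each of them (1.45 ± 0.52). The stress genes of R273H lay closer to the type 1 lines. HMOX1 was at 4.39 FPKM with DMSO and 52.3 with ATO and MT2A at 65.1 and 354 FPKM, while the log2 difference was 0.68 for NRF2 targets and 1.35 for metallothioneins. HMOX1 with ATO was nonetheless below the type 1 lines, which held 76.6 to 501.1 FPKM, and the log2 difference of FTH1 (2.16) was the lowest of the 11 mutant lines. G2/M genes had a mean log2 difference of 0.24 in R273H against -0.38 ± 0.22 in the type 1 lines, and G1/S genes of -0.22 against -0.49 ± 0.21. MCM7 was lower by a log2 of -1.24 in the R273H pair.

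By limma 0 genes differed between the R273H and the type 1 responses. An unadjusted p under 0.05 was reached by 585 of 11147 genes, where 557 would be expected by chance. The count of 0 became 1 with a pseudocount of 0.1 and 264 without the expression filter. Examples of values are the differences for CDKN1A (-2.01 ± 0.83, SE), ZMAT3 (-1.97), BTG2 (-1.81), MDM2 (-1.75) and UBE2C (1.22), each with adjusted p = 0.862. Camera at its preset correlation placed 9 of 22 lists apart. With an estimated correlation 0 did, the adjusted p of these 9 lists lying between 0.453 and 0.469, and fry passed 0 lists. Lower in R273H were the p53 targets (mean difference -0.53, camera adjusted p = 2.6e-12; 0 genes over all genes and 2 adjusted over the list alone), the arrest and feedback targets (-1.32, 3.1e-08; 0 and 6), the apoptosis targets (-0.62, 1.8e-04; 0 and 1) and the repair and metabolism targets (-0.46, 1.8e-04; 0 and 1). Higher were the G2/M genes (0.62, 1.2e-22; 0 and 8 adjusted over the list alone), G1/S genes (0.28, 4.2e-07), ATF4 targets (0.32, 6.2e-06), proteasome genes (0.14, 6.2e-06) and cholesterol synthesis genes (0.36, 5.7e-07), and in these last 4 lists 0 genes passed either over all genes or adjusted over the list alone. The NRF2 targets (mean -0.07, median 0.07, camera adjusted p = 0.524, tested higher) and the glycolysis genes (mean -0.02, median 0.02, adjusted p = 0.262, tested higher) differed in sign between their measures, and interferon genes had a mean of 0.06 and a median of -0.01. Placing R273H among the 11 lines gave exact permutation p-values of 0.182 for the p53 targets (adjusted 0.667) and 0.0909 for the arrest and feedback targets (adjusted 0.5), the smallest p that 11 lines allow being 0.0909. With 1 pair of libraries the spread of the R273H response is unknown and was taken to equal that of the type 1 lines.

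Within the R273H pair, 99 genes were at least 2-fold higher and 100 at least 2-fold lower with ATO. The total of 199 depended on the treatment of low values, being 681 without the expression filter, 42 with a filter of 5 FPKM, and 300 and 125 with pseudocounts of 0.1 and 1. The 10 highest differences among genes with 5 FPKM or more belonged to HMOX1 (3.43), MT2A (2.44), TRGJP2 (2.34), FTH1 (2.16), TRGJP1 (1.81), MIR6512 (1.75), Y_RNA (1.74), the heme transporter gene SLC48A1 (1.65), MT1X (1.60) and TNFRSF14 (1.59). The 10 lowest belonged to MIR5787 (-4.05), MIR25 (-2.25), SNORD12C (-2.19), MIR3176 (-2.13), SNORA11F (-1.89), MIR5581 (-1.58), SNHG4 (-1.37), EFNA3 (-1.25), MCM7 (-1.24) and SNORD15B (-1.23). Several of these small RNAs lie inside longer genes, such as MIR25 in MCM7 and SNORD15B in RPS3. Those of 300 nt or less rest on few reads, from an estimated 7 with DMSO and 0 with ATO for MIR5787, whose value is set by the pseudocount, to 25 and 4 for MIR25. The median log2 difference was 1.43 for metallothioneins and 0.44 for NRF2 targets, each above all of 10000 matched random lists. For p53 targets it was 0.16, also above all random lists, and it fell to 0.03 without the expression filter. Of these targets 40 of 65 were above 0 and 0 of 65 at least 2-fold higher. The p53 sublists did not stand out in this way. Arrest and feedback targets (0.20, 6 of 9 above 0) lay above 96.75% of random lists. Repair and metabolism targets (0.008, 7 of 13) lay above 51.8% and apoptosis targets (-0.13, 3 of 10) above 6.69%. Random lists take no account of the correlation between members of a list. Monocyte markers (median 0.43, 10 of 13 above 0), interferon genes (0.46, 8 of 10) and G2/M genes (0.24, 23 of 29) also lay above all random lists, and G1/S genes (-0.18, 4 of 28) lay above 0.070% of them.

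The wild-type line against the p53-null line, both untreated, compares the references for normal and absent p53, with 1 library each. An effect of p53 cannot be told apart from other differences between these cultures. The cell cycle arrest gene CDKN1A was at 74.5 FPKM in wild-type and 7.38 in p53-null cells, and BTG2 at 19.2 and 2.66 FPKM. Among the 10 highest log2 differences were those of CDKN1A (3.25), BTG2 (2.64), SBF2 (2.63), NCF1 (2.58), TRIM22 (2.51), CD52 (2.35), MIR1249 (2.14), MDM2 (2.12) and MYBPH (2.05). The 10 lowest were those of SNORA66 (-2.92), HLA-DRA (-2.65), TRGJP1 (-2.51), SNORD15B (-2.27), MIR3153 (-2.25), MIR3186 (-2.08), MIR5587 (-1.62), EGR1 (-1.24), HES4 (-1.23) and SNORA5C (-1.23). The short genes among these (MIR1249, TRGJP1 and the small RNAs from SNORA66 to SNORA5C) rest on an estimated 1 to 24 reads per library. NCF1, a subunit of the phagocyte oxidase, has closely related pseudogenes that can share its reads. The median log2 difference over p53 targets was 0.49, with 59 of 65 members above 0, and over arrest and feedback targets 1.73, with 9 of 9 above 0. G1/S genes had a median of -0.59 with 0 of 28 above 0, G2/M genes of -0.31, cholesterol genes of -0.41 and monocyte markers of 0.72. The p53, arrest and monocyte medians lay above, and the G1/S, G2/M and cholesterol medians below, all of 10000 matched random lists. Random lists give no spread between cultures. In untreated type 1 lines the list mean minus p53-null reached 1.11 for monocyte markers, against 0.77 in wild-type. For cholesterol genes it reached -0.50, against -0.42. For the p53, arrest, G1/S and G2/M lists no untreated type 1 line lay as far from p53-null as wild-type. In total 138 genes were at least 2-fold higher and 84 at least 2-fold lower, each from a single pair of libraries. Their total of 222 was 754 without the expression filter, 62 with a filter of 5 FPKM, and 345 and 138 with pseudocounts of 0.1 and 1.

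Untreated type 1 lines against p53-null cells ask what goes with the mutants without the drug. The p53 target genes CDKN1A (21.9 ± 30.7 against 7.38 FPKM) and MDM2 (4.76 ± 1.10 against 3.35 FPKM; SD, n = 10) had log2 differences of 0.93 ± 0.97 and 0.42 ± 0.27 (SE), both with a limma adjusted p of 1.00. The CDKN1A mean rests largely on P142L, without which it was 12.4 ± 4.84 FPKM and the log2 difference 0.61 ± 0.48 (limma adjusted p = 0.997). By limma 0 genes passed, and 188 had an unadjusted p under 0.05, where 557 would be expected by chance. The count of 0 became 1 with a pseudocount of 0.1 and 536 without the expression filter. By camera at its preset correlation 7 of 22 lists passed, but 0 did with an estimated correlation, where the adjusted p was 0.878 for the repair list and 0.911 for the other 6. Camera passed 3 lists with quantile normalization (p53 targets, repair and metabolism targets, and cholesterol synthesis) and 0 without the expression filter, and fry passed 0. At the preset correlation the higher lists were the p53 targets (mean 0.12, adjusted p = 0.0027), arrest and feedback targets (0.31, 0.012) and repair and metabolism targets (0.14, 0.0041). Lower were the G1/S (-0.09, 0.0035), proteasome (-0.08, 0.0062), cholesterol (-0.16, 0.0027) and ribosomal genes (-0.09, 0.0035). In each of these lists 0 genes passed, over all genes and adjusted over the list alone. NF-kB targets had a mean of -0.02 and were tested higher (adjusted p = 0.85). The mean of the arrest and feedback targets minus p53-null was 1.19 in untreated P142L and 0.01 to 0.51 in the other lines, and without P142L and V272A only the G1/S, proteasome and ribosomal lists passed, all lower, so that no p53 list did. The comparison rests on the only p53-null library.

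Untreated type 1 lines against wild-type cells had a lower mean of the p53 target list and higher means of the G1/S and G2/M lists, but few single genes passed. Over all genes 6 of 65 p53 targets were lower, and 6 of 28 G1/S and 1 of 29 G2/M genes were higher. Camera passed these lists at its preset correlation and not with an estimated correlation (adjusted p = 0.077, 0.077 and 0.21). MDM2 was lower by a log2 of -1.70 ± 0.27 (SE, limma adjusted p = 0.0090), FDXR, a mitochondrial reductase gene, by -1.47 ± 0.21 (0.0065), DRAM1, an autophagy gene, by -1.11 ± 0.15 (0.0053) and XPC by -0.86 ± 0.15 (0.016). CDKN1A differed by -2.32 ± 0.97, which did not pass (limma adjusted p = 0.230), but without P142L the difference was -2.64 ± 0.48 and passed (limma adjusted p = 0.0091). Higher in the type 1 lines were CDC45, a replication factor (0.75 ± 0.08, adjusted p = 0.0048), MCM7 (0.54 ± 0.09, 0.011) and BIRC5, the survivin gene (0.78, 0.0081). The 6 highest differences past the threshold were those of SNORD6 (3.39), MIR4258 (2.36), SNORA66 (2.18), the polyamine enzyme gene ODC1 (0.93 ± 0.13, adjusted p = 0.0061), MIR25 (0.88) and ACOT7 (0.82 ± 0.12). SNORD6 was listed at 0 in wild-type and MIR4258 at 0 in wild-type and p53-null cells, so their values are set by the pseudocount. The 4 small RNAs lie inside TAF1D, CKS1B, RPL5 and MCM7 and rest on an estimated 0 to 27 reads per untreated library. The 6 lowest were those of CD52 (-2.20 ± 0.47), MYBPH (-1.93), APOBEC3H (-1.83), KLHL30 (-1.74 ± 0.30), MDM2 and the integrin gene ITGAL (-1.62 ± 0.20, adjusted p = 0.0048). CD52 (limma adjusted p = 0.045), MYBPH (0.049) and APOBEC3H (0.047) passed narrowly. With a pseudocount of 0.1 none of the 3 passed (0.055, 0.058 and 0.183), and neither did CD52 (0.085) and MYBPH (0.088) without the expression filter or APOBEC3H (0.067) with quantile normalization.

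In total 112 genes differed from wild-type by limma, 45 higher and 67 lower in the type 1 lines. The balance turned with median-of-ratios scaling (105 higher, 65 lower) and quantile normalization (111 higher, 96 lower). The count depended on single lines. It was 56 without L130V, 54 without L130F, 54 without L130R, 55 without V143M, 67 without M237V, 68 without F270V, 234 without F270I, 270 without V272A and 599 without P142L. Of the p53 targets 0 were higher and 6 lower over all genes, and 1 higher and 34 lower adjusted over the list alone (mean -0.55, camera adjusted p = 2.2e-14, adjusted p = 0.077 with an estimated correlation). Arrest and feedback targets (mean -1.27, camera adjusted p = 4.1e-06, adjusted p = 0.118 with an estimated correlation) had 2 lower genes over all genes and 8 adjusted over the list alone. Repair and metabolism targets (mean -0.48, 3.2e-05, adjusted p = 0.077 with an estimated correlation) had 2 and 7, and apoptosis targets (mean -0.34, 0.027, adjusted p = 0.245 with an estimated correlation) 0 and 4, with 1 higher adjusted over the list alone. Of 28 G1/S genes 6 were higher over all genes and 22 adjusted over the list alone (mean 0.48, camera adjusted p = 1.9e-22, adjusted p = 0.077 with an estimated correlation), and of 29 G2/M genes 1 and 15 (mean 0.37, 3.3e-13, adjusted p = 0.21 with an estimated correlation). Monocyte markers were lower (mean -0.69, camera adjusted p = 0.0035, adjusted p = 0.376 with an estimated correlation; 0 over all genes and 2 adjusted over the list alone). Metallothioneins (0.30), heat shock genes (0.11), ATF4 targets (0.25), endoplasmic reticulum chaperones (0.16), proteasome (0.20), cholesterol (0.26), glycolysis (0.17) and ribosomal genes (0.15) had higher means by camera. None of them passed with an estimated correlation. Camera does not match genes on expression. In wild-type minus p53-null, random lists matched to the ribosomal genes had medians mostly between -0.27 and -0.10. There the heat shock, endoplasmic reticulum, glycolysis and ribosomal medians lay above 72.1%, 5.9%, 27.5% and 6.98% of matched lists. The metallothionein, ATF4, proteasome and cholesterol medians lay above 0.21% or fewer. Lower abundant genes in the wild-type library may thus enter these calls, which was not tested. NRF2 targets (mean -0.01, median 0.04, tested higher, adjusted p = 0.37) did not pass. In all 15 of 22 lists passed camera, 10 higher and 5 lower, while 0 passed with an estimated correlation and 6 passed fry.

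The ATO response of the type 1 lines was compared across genes with wild-type minus p53-null to ask how much of the wild-type expression it shares. The 138 genes at least 2-fold higher in wild-type than p53-null included 89 that rose with ATO in the type 1 lines, where 48.5 would be expected by chance, and 4 that fell (38.9 expected). CDKN1A, BTG2, MDM2, TRIM22 and SBF2 were among the 89. Of the 84 genes at least 2-fold lower in wild-type, 22 fell with ATO (23.7 expected) and 13 rose (29.5 expected), and HLA-DRA was among those that fell. The Spearman correlation across genes was 0.48 for the mean response of the type 1 lines, and 67.0% of genes had the same sign. In single lines it was 0.398 ± 0.130 (SD, n = 10), from 0.088 in M237V to 0.52 in L130F, and it was 0.151 in R273H (exact placement p = 0.182 among the 11 lines). Without the expression filter the type 1 mean was 0.221 and R273H was at 0.074. Over the 222 genes at least 2-fold apart between wild-type and p53-null, the correlation in single type 1 lines was 0.397 ± 0.076 (SD, n = 10). R273H was at 0.283 over these genes, above V272A (0.223) and below the other type 1 lines. Genes are not independent replicates, and the wild-type difference rests on 1 library for each genotype.

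Whether lines with a larger p53 target change also differ more in cell cycle genes was tested over the 10 type 1 lines. The p53 target change and the G1/S change had Pearson's r = -0.70 (permutation p = 0.0244, adjusted 0.0518 over 3 relations, of which 2 are given here) and Spearman's rho = -0.45 (p = 0.190), and over the 8 lines without V272M and F270I r was -0.54 (exact permutation p = 0.172), so the relation passed neither the correction nor the test over fewer lines. For the G2/M change r was -0.58 (permutation p = 0.0795, adjusted 0.0795) and rho -0.62 (p = 0.0606), and without the same lines r was -0.47 (exact permutation p = 0.239). Both changes of a line come from the same pair of libraries. Lines mutated at the same residue had responses with a mean correlation of -0.036 ± 0.162 over 5 pairs after the common response was removed, against -0.119 ± 0.116 over the other 40 pairs, a difference that did not pass (0.084, permutation p = 0.153). Subtracting the mean of the same 10 lines pushes these correlations below 0, so negative values do not show opposed responses. Before the subtraction the responses of any 2 type 1 lines correlated at 0.42 to 0.76.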

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

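The tests of arsenic exposure and ordinary variation in R273H, and of carry-over, exchange and the genes that differ 2-fold in wild-type in P142L, were chosen only after the results were seen.

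The response of R273H to ATO differed from that of the type 1 lines in 9 gene lists by camera. The mean log2 difference, R273H minus type 1, was -0.53 for p53 targets, -1.32 for arrest and feedback targets, -0.62 for apoptosis targets, -0.46 for repair and metabolism targets, 0.62 for G2/M genes, 0.28 for G1/S genes, 0.32 for ATF4 targets, 0.14 for proteasome genes and 0.36 for cholesterol synthesis genes. With an estimated correlation 0 of these lists passed, and limma passed 0 single genes (264 without the expression filter). An unadjusted p under 0.05 was reached by 585 genes, where 557 would be expected by chance.

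Weaker exposure of the R273H culture to arsenic could lower every drug response alike, but the metallothionein list of R273H changed by 87.6% and the NRF2 list by 90.2% of the type 1 mean, while the p53 target list changed by 14.98%, which argues against exposure as the whole cause. HMOX1 at 69.7% and FTH1 at 75.3% of the type 1 mean were the lowest of the 11 lines, so a somewhat weaker exposure stays open as a part of the difference. Ordinary variation between single cultures cannot be told apart from an effect of the mutant, because 11 lines allow no placement p below 0.0909 and 1 pair of libraries gives no spread for R273H (treated as the odd line in the same way, V272M had 1508 genes at an unadjusted p under 0.05). The type of the mutant, which the labels name, stays open as the biological explanation and has no second type 3 line to test it.

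Untreated P142L lay far from the other 9 untreated type 1 lines in several lists, measured as the mean log2 level minus p53-null. It stood at 0.41 for p53 targets (others 0.01 to 0.20), 1.19 for arrest and feedback targets (0.01 to 0.51), -0.30 for G2/M genes (-0.08 to 0.15), -0.44 for ATF4 targets (-0.10 to 0.15), 1.11 for monocyte markers (-0.08 to 0.08), 0.35 for azurophil granule genes (-0.14 to 0.12), 0.43 for interferon genes (-0.19 to 0.10) and 0.59 for NF-kB targets (-0.21 to 0.03). CDKN1A in that library was at 108.3 FPKM (others 6.18 to 21.1) and HMOX1 at 12.01 FPKM (3.28 to 7.16). Wild-type minus p53-null was 0.67, 1.59, -0.34, -0.30, 0.77, 0.24, 0.25 and 0.12 for these 8 lists in the same order, so P142L had the sign of wild-type in each of them, and in 16 of all 22 lists. Both differences subtract the same p53-null library, which pushes their signs to agree. The 8 lists were also picked for a gap of P142L, so these signs do not test a likeness to wild-type. A gap of this kind was found in 14 of 96 groups of values, where a rate of 1 in 20 would give about 4.8. That rate assumes normally distributed values, which FPKM values near the floor, such as those of GDF15, need not be. The groups share libraries and genes, and most of the gaps belong to P142L, so the excess does not count separate departures.

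RNA or cells carried over from the ATO-treated P142L culture could raise the p53 targets of the untreated library, and the CDKN1A level would need a share of 56.8% treated RNA. HMOX1 allows 1.55%, MT2A 6.49% and FTH1 11.01%, which argues against carry-over as the whole cause, although FTH1 met the bound set for this test only narrowly. An exchange of this library with another line is argued against by its correlation with its own treated partner, 0.606, when the next treated library reached 0.160. A partly wild-type-like expression of P142L is a biological hypothesis on which 2 tests disagree. Over 11082 genes other than p53 targets its untreated deviation correlated with wild-type minus p53-null at 0.043, below F270V (0.222), M237V (0.211) and F270I (0.192), which is against it. Only 209 of these genes differ at least 2-fold between wild-type and p53-null, so this test dilutes such a likeness, and over those 209 P142L was the highest at 0.199, narrowly above F270I (0.144) and V272A (0.143), so the hypothesis stays open. A difference between clones or cultures, for which the labels give no information, was not tested and stays open.

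In 4 further groups a single library stood apart from the other 9 type 1 lines. Untreated F270I stood at 0.29 above p53-null in glycolysis and hypoxia genes (others -0.10 to 0.03). BAX in untreated V272A was at 43.1 FPKM (20.8 to 32.6). GDF15 in ATO-treated P142L was at 2.38 FPKM (0 to 0.59). GAPDH in untreated V272M was at 2030 FPKM (1653 to 1801).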

How the results depend on the processing

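The settings that leave out P142L with V272A, or L130F, L130R and F270I, were chosen after seeing the data. So were the score on 13 targets and leaving out P142L for the always-named genes. Of the alternative list tests, those with the estimated correlation or median-of-ratios scaling were set beforehand, and the others were added later. The cause of the changes given here was not tested, except where fewer lines or another number of genes entered by construction.

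Of 161 results of comparisons under the alternatives set beforehand, 130 stayed within their bounds and 31 moved, and of 42 added later 37 were within them and 5 moved. The ATO response stayed between 4721 and 7871 genes, and between 6683 and 7107 with any line left out, but fell to 145 with a 2-fold minimum. The fit without the line block gave 6263. The p53 target score of the type 1 lines ranged from 0.48 to 1.43 and its difference in R273H from -1.28 to -0.34, with no change of direction. The score passed its exact test in each setting, while the placement of R273H cannot pass in any.

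With a pseudocount of 0.1, R273H against type 1 went from 0 genes to 1, type 1 against p53-null from 0 to 1, wild-type against p53-null from 222 to 345 and the R273H pair from 199 to 300. With a pseudocount of 1 the last 2 gave 138 and 125. Without the expression filter these 4 gave 264, 536, 754 and 681, type 1 against wild-type 741, the mean correlation with the wild-type expression 0.221 (0.398 with it; R273H 0.074 against 0.151), the p53 target median of the R273H pair 0.03 (0.16 with it), and the list tests of type 1 against p53-null 0. With a filter of 5 FPKM the single pairs gave 62 and 42 genes and type 1 against wild-type 188. Type 1 against wild-type, 112 genes, gave 170 with median-of-ratios scaling, 207 with quantile normalization, 54 to 599 with any line left out, 1083 without P142L and V272A, and 46 without L130F, L130R and F270I.

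With an estimated correlation 0 lists passed in each of the 4 list comparisons. At the preset correlation, heat shock, glycolysis, ribosomal and mitochondrial lists gained a call for R273H against type 1 without L130F, L130R and F270I. The ribosomal list gained it with quantile normalization too. Of the 7 lists of type 1 against p53-null, 3 passed with quantile normalization (p53 targets, repair and cholesterol) and 3 others without P142L and V272A (G1/S, proteasome and ribosomal), where no p53 list passed. Against wild-type, the apoptosis call was lost without the expression filter, with a filter of 5 FPKM, and without L130F, L130R and F270I. The heat shock call was lost without the filter, with either other scaling, and without P142L and V272A. Endoplasmic reticulum, glycolysis and ribosomal calls were lost with quantile normalization, and the metallothionein call without P142L and V272A. Azurophil granule, immediate early, interferon and histone genes each passed in a single setting. Glycolysis genes in R273H against type 1 turned from -0.02 to 0.067 (camera adjusted p = 0.0416) without L130F, L130R and F270I. Of 304 list results added later 292 were the same, 4 weaker, 7 stronger and 1 reversed, of 88 set beforehand 62 were the same and 26 weaker, and of 233 results of named genes 227 were the same and 6 weaker, those of CD52, MYBPH and APOBEC3H against wild-type. Of 24 results of always-named genes without P142L 21 were the same, 2 stronger and 1 reversed. CDKN1A (-2.64, adjusted p = 0.0091) and FAS (-0.76, 0.0487) against wild-type passed, and HMOX1 against p53-null, which passed in neither case, turned from 0.0675 to -0.0654. The apoptosis list (camera adjusted p = 0.0554) and the endoplasmic reticulum list (0.0902) lost their ATO calls with the 5 FPKM filter, and the latter (0.0774) and the proteasome list (0.287) with quantile normalization. Interferon and histone lists had too few genes at 5 FPKM for a value. The alternative for read counts was not run because the table holds FPKM.

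At this depth 3 reads in a 1 kb gene are worth 0.149 to 0.216 FPKM, so TP53I3 and GDF15 in most libraries lie near or below what can be measured.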

Other observations

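The within-pair splits, the random splits and the comparison of the missing part of the R273H response with wild-type cells were set before their results were seen, and the relations with the cell cycle genes were tested only after.

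P142L had 8 genes at least 2-fold above all other 9 type 1 lines with DMSO and again with ATO. The calgranulin gene S100A9 was at 79.9 FPKM untreated and 134.5 with ATO, when the other lines held 12.8 to 20.2 and 23.3 to 40.9 FPKM. The neutrophil chemoattractant gene CXCL8 was at 20.1 and 27.6 FPKM, CHI3L1 at 437.6 and 428 FPKM, the IgA receptor gene FCAR at 17.9 and 21.6 FPKM, CAMP, which encodes an antimicrobial peptide, at 22.9 and 27.2 FPKM, and CYBB, a subunit of the phagocyte oxidase, at 13.4 and 10.9 FPKM. S100A8 was at 21.7 and 41.8 FPKM. CXCL8 was at 4.91 FPKM in wild-type and 5.63 in p53-null cells, and the other genes named were higher in wild-type than in p53-null cells. These were CHI3L1 (336.2 and 119.5 FPKM), S100A9 (31.7 and 18.6), CAMP (13.4 and 6.37), CYBB (8.35 and 1.75), FCAR (6.92 and 2.25) and S100A8 (5.89 and 2.06), each from a single library per genotype.

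V272A had 4 such genes, among them the stomach gene GKN1 at 15.01 and 16.7 FPKM, which was listed at 0 in all other libraries, and 1 gene at least 2-fold below the other lines, MIR4442, at 62.3 and 67.6 FPKM. The other 8 type 1 lines had 0 genes of either kind. MT2A with ATO was at 859 to 958 FPKM in L130F, L130R and F270I and at 269 to 412 FPKM in the other 7 type 1 lines. The genes named here were chosen after their values were seen.

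Chance is unlikely to account for the number of genes called for ATO in the type 1 lines. With 100 splits no share below 1 in 100 can be reached. The splits also cannot separate ATO from a handling difference shared by all treated cultures, on which the labels give no information. Among 100 splits that exchange DMSO and ATO within pairs, 1, the real one, called 7056 genes or more, and the highest other called 4659 after exchanging 1 pair, while 95 others called 0. Among 100 random splits of the 20 libraries without the line block, 1, the real one, called 6263 genes or more, and the highest other called 269.

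The part of the type 1 response that R273H lacks may resemble the wild-type expression. Type 1 mean minus R273H correlated across genes with wild-type minus p53-null at 0.447, but M237V in the place of R273H gave 0.505. The other type 1 lines gave -0.364 (V272M) to 0.307 (V143M). The prediction that R273H would give the highest value was not borne out, so the resemblance was not particular to R273H. This comparison of lines does not test the resemblance itself, which stays open.

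Lines with a larger p53 target change may have a larger fall of cell cycle genes. Over the 10 type 1 lines the p53 target change correlated with the G1/S change at r = -0.70 (permutation p = 0.0244, adjusted 0.0518) and with the G2/M change at r = -0.58 (permutation p = 0.0795). Neither passed the correction, and without V272M and F270I the r was -0.54 and -0.47 (exact permutation p = 0.172 and 0.239), so 10 lines leave this open.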
